A study of Drosophila melanogaster with 2 samples.

How the data were processed

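The data are ChIP-seq peak lists from whole Drosophila melanogaster embryos of 0 to 24 h that carried a transgene for Araucan fused to enhanced green fluorescent protein (ara-eGFP). Chromatin was sheared by sonication to fragments of 200 to 800 bp and precipitated with an antibody against the fluorescent protein, per the labels. The labels give 1 group with 2 biological replicates, so that no comparison between groups was made. No paired analysis was possible because there is only 1 group. The labels place all coordinates on dm6. The aligner, the peak caller and the sequencing depth are not given in the sources used here, and control libraries were not used here.

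The authors deposited, for each replicate, a full ranked peak list and a thresholded list, and for the series ranked lists, a conservative thresholded list and another thresholded list. The signal of each peak is the authors' own value, its normalization is not given in the sources used here, and it was used to rank, describe and filter peaks within a list. The deposited score runs up to 1000, and every thresholded list held only peaks with a score of 830 or more. The deposited ranked lists also hold a −log10 value for each peak, taken here as that of the global irreproducible discovery rate, a measure of how poorly a peak's rank repeats between replicates. The lowest such value among the conservative peaks was 2. All 4716 conservative peaks were found in 1 series-wide ranked list of 150015 peaks. For 119682 of its peaks the first set of replicate values equalled a peak of replicate 1's own list, and for 115671 peaks the second set equalled a peak of replicate 2's list, so this list compares the true replicates. All 5483 peaks of the other thresholded list were found in a ranked list of 152526 peaks whose values equalled no peak of either replicate.

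The conservative list was the main peak set, a choice made before the data were examined together with the tests, the gene lists, the motifs and the alternatives not marked otherwise. Analyses covered the 6 assembled arms 2L, 2R, 3L, 3R, 4 and X, and summits were used as 1-based positions. Annotation came from Ensembl release 115 (BDGP6.54, the same sequence as dm6), without transposable elements. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Intervals of shares are exact (Clopper-Pearson) at 95% and cover counting error only. Peaks of 2 lists were called shared when they overlapped by at least 1 bp, with chance taken from 1000 circular shifts of a list along each arm. Replicate signals were compared between peaks of the replicates' own ranked lists that were each other's nearest and had summits within 150 bp. Features were assigned in the order promoter (within 500 bp of an annotated transcription start site, TSS), 5' UTR, 3' UTR, coding exon, other exon, intron and intergenic, and tested against 1000 circular shifts, 2-sided, for which 0.001 is the smallest p possible. Arms were tested by exact binomial tests.

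A gene's locus was the gene with 5 kb on each side. For 21 gene lists, the number of members with a summit in the locus was compared with 13945 protein-coding genes in 20 bins of locus length by an exact 2-sided stratified test. Of the fixed symbols, 5 differed from the annotation's and were matched through older names. Motif shares in 101 bp windows centred on summits were compared with windows 500 bp to each side by 2-sided Fisher's exact tests, with 0.5 added to each cell for the odds ratio where a count was 0 and for all intervals. P-values were adjusted by the Benjamini-Hochberg method over the 6 arms, the 21 lists or the 14 motifs. Trends with signal used Spearman's rho with 100000 permutations, for which 1e-05 is the smallest p possible.

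The genes named are ara, caup and mirr with every peak in their loci, and the genes with the TSS nearest to the 25 peaks of highest signal. In a list past the adjusted threshold, the 4 members with the highest signal and up to 4 without a summit, in alphabetical order, are also named. The result of 1 such member is not reported here. In each other list, the 2 members with the highest signal are named, with the lower coordinate first in ties. Any further name was chosen after its values were seen. On simulated data the list test called 4.4% of 500 random lists of 20 genes at an unadjusted 0.05 and 96.2% of lists with a planted ratio of 2. Bound loci were drawn there gene by gene, so these rates do not cover lists whose neighbouring loci share summits. A planted promoter share of 48.4% was recovered as 48.4% of 4000 simulated summits. With a motif planted in 10% of 1999 windows, all 268 windows that then held it were counted, for an odds ratio of 4.20. The promoter and motif checks test the counting alone, because the planted summits and sites were promoters and motifs by construction.

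Alternatives were the other thresholded list, the stronger peaks alone, each replicate's own list (leaving the other replicate out), other promoter distances, other locus and matching rules, and other motif windows and backgrounds. Chosen after seeing the data were leaving out peaks under a signal of 30, taking all ranked peaks at the same score, matching genes on TSSs in the locus, 7 gene families picked by symbol, 8 further motifs, and the GC share of summit windows. Peaks off the 6 arms were left out of the tests because the annotation of those scaffolds is sparse.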

Results

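Binding of Araucan, a homeodomain transcription factor of the Iroquois complex, was profiled by ChIP-seq against a fluorescent tag in 2 biological replicates of whole embryos aged 0 to 24 h. The conservative list held 4716 peaks, 4706 of them on the assembled arms of dm6, with a median width of 324 bp and a median signal of 96.1 in the authors' units. The other thresholded list held 5483 peaks. Replicate 1's own thresholded list held 2402 peaks and replicate 2's held 4136. The files give no read counts, so the depth behind each signal is unknown, and with 1 group the comparisons are between replicates, genomic regions, genes and sequences.

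The Iroquois complex itself held many Araucan peaks, most of them of modest signal. Its members ara, caup and mirr, which encode related homeodomain factors with roles in sensory organ, wing vein and eye patterning, lie side by side on 3L, and all 3 had summits in their loci. From 25 kb before ara to 25 kb past mirr (3L, 12555672 to 12735249), 26 summits fell in 179.6 kb, against a median of 6 in 100000 random windows of that length on 3L. As many or more were found in 2.21% of those windows, a count made after the data were seen. Most of the 26 had a signal below the median of the conservative list (96.1), and most were not listed in both replicates. An effect of the ara-eGFP transgene on read density at this locus cannot be told apart, because control libraries were not used here.

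The ara locus (gene at 12580672 to 12596018, plus strand, FBgn0015904) held 6 peaks. The highest, at 12590343 to 12590666 in an intron, had a signal of 121.1 and was listed in both replicates, at 70.9 in replicate 1 and 50.2 in replicate 2. The other intronic ara peaks had summits at 12586643 (signal 81.8), 12587733 (64.4) and 12588443 (95.7). A further summit at 12580614 (71.5) lay in the promoter, and that at 12577734 (69.2) was intergenic, upstream of the gene. The caup locus (gene at 12609631 to 12621798, plus strand, FBgn0015919) held 5 peaks. The intronic peak at 12619005 to 12619328 reached 166.9 and the intergenic peak with its summit at 12606480 reached 162.2, and both were listed in both replicates. Another intronic summit lay at 12616573 (129.3), and the 5' UTR held a pair at 12610405 (52.8) and 12610650 (44.8). The mirr locus (gene at 12693639 to 12710249, plus strand, FBgn0014343) held 1 peak, intronic, at 12706455 to 12706778 with a signal of 74.7, listed in replicate 1 alone (39.8). The strongest peak of the complex was higher than 77.3% of conservative peaks. For genes of their length 1.86 bound loci were expected, and with 3 members even the highest possible count does not pass this test (exact p = 0.291, adjusted p = 0.68). Matched on TSSs in the locus, a choice made after seeing the data, the ratio was 4.53 (exact test, adjusted p = 0.0278). The expected count was then 0.662, below the 1.31 expected without any matching, so locus length was not allowed for.

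**Figure D1:**
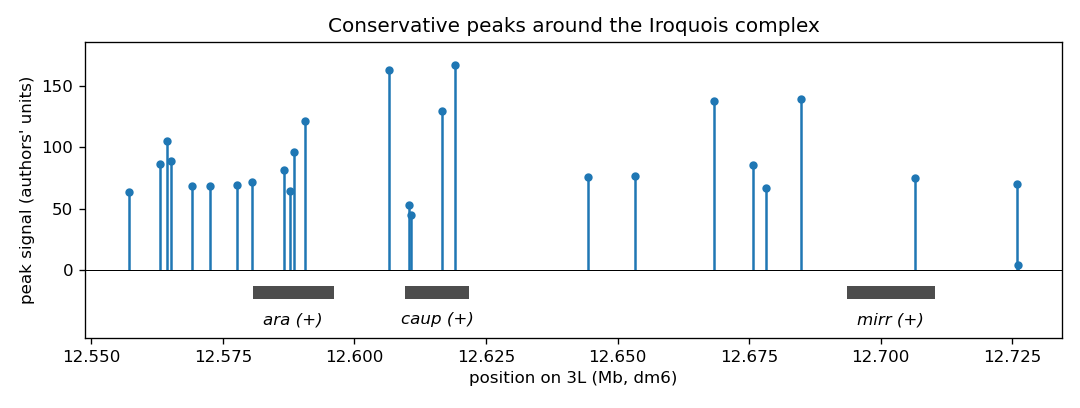
Conservative peaks across the Iroquois complex on 3L (dm6 position in Mb), each line a summit with its height the peak signal in the authors' units and grey bars the genes with their strand. The 26 summits lie upstream of ara, over and between ara and caup, and before, within and beyond mirr. The highest, in a caup intron, reaches 166.9.

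The strongest Araucan peaks lay mostly at promoters, and none of the 25 strongest lay in the Iroquois complex. The 25 strongest peaks had signals from 1036 to 2240, 20 of them were in promoters, 15 had a summit within 150 bp of a protein-coding TSS, and all 25 were listed in both replicates. The highest, 2240 at X 2703749 to 2704026, had its summit 39 bp from the TSS of Ugalt, a UDP-galactose transporter of the Golgi. Peaks at CG14100 (1903, 90 bp away) and at ph-p, a Polycomb group gene (1832, 500 bp away), came next. The peak nearest px, a gene of wing vein patterning, reached 1823 at 211 bp. Other nearest genes were Tcs5, a gene of tRNA modification (1644, 96 bp), PNPase, the mitochondrial polynucleotide phosphorylase (1397, 72 bp), and RluA-1, a pseudouridine synthase gene (1052, 166 bp). The mitochondrial ribosomal protein genes mRpL41 (1188, 129 bp) and mRpL23 (1098, 88 bp) also had a summit close to the TSS. The summit nearest eEF1gamma, a translation elongation factor gene, was 5724 bp from its TSS (1142). Chro, which encodes the chromatin and spindle protein Chromator, had a signal of 1423 at 93 bp, and the arginine methyltransferase gene Art3 1522 at 125 bp. CenG1A, an ARF GTPase regulator (1285, 99 bp), and Fkbp14, a peptidyl-prolyl isomerase gene (1153, 104 bp), had similar distances. The uncharacterised genes CG18549 (1387), CG1888 (1352), CG7601 (1325), CG5611 (1277), CG13921 (1197) and CG3552 (1036) all had the summit within 218 bp of a TSS. Away from promoters, intronic summits lay nearest CG11050 (1640, 1026 bp), CG32772 (1161, 1264 bp) and the chromatin kinase gene Tlk (1147, 2330 bp). Intergenic ones lay nearest CG13323 (1228, 11913 bp) and CG31668 (1060, 3755 bp).

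Genome-wide, Araucan summits gathered just upstream of TSSs and avoided transcribed sequence that encodes protein. Promoters held 1878 of 4706 summits, 39.9% (95% interval 38.5 to 41.3), against 13.6% after circular shifts, a ratio of 2.94 (permutation p = 0.001, the smallest possible). Coding exons held 135 summits (2.87% against 13.1%) and 3' UTRs 40 (0.85% against 5.0%), both with permutation p = 0.001. The coding exon share was lower still without replicate 1 (1.04%), without replicate 2 (1.17%) and in the stronger peaks (0.17%). Intergenic sequence held 16.9% against 27.4% (permutation p = 0.001). Introns held 1775 summits, 37.7% against 39.3%, a difference within the shifts (permutation p = 0.135). Of 1725 summits within 500 bp of a protein-coding TSS, 73.4% were upstream, with a median position of -93 bp and quartiles at -179 and 9 bp. A summit lay within 500 bp of a TSS for 2099 of 13945 protein-coding genes.

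**Figure D2:**
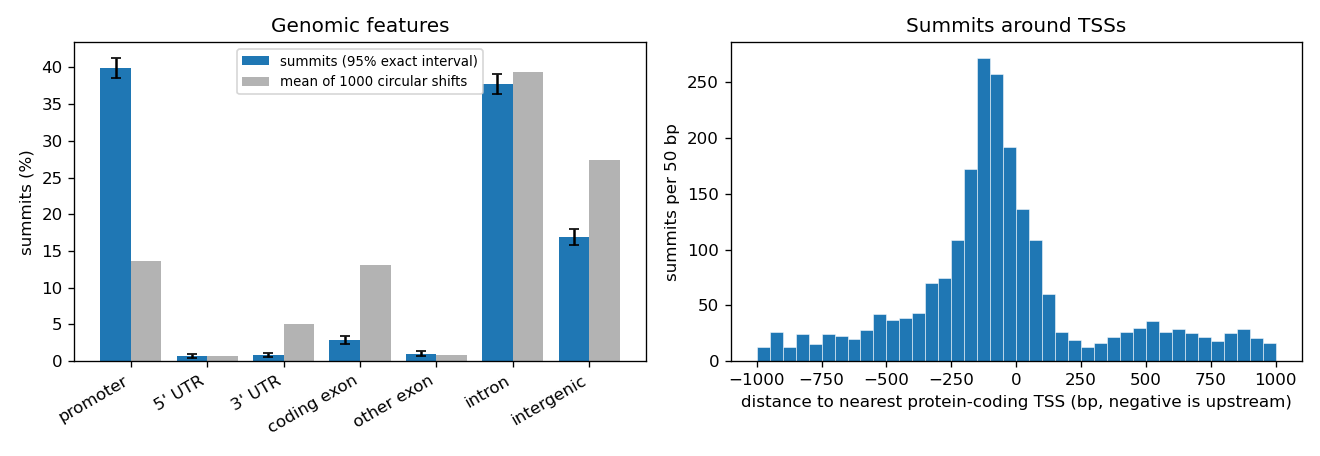
Left, the share of 4706 summits in each feature class (%, bars with 95% exact intervals) beside the mean of 1000 circular shifts in grey. Right, summits per 50 bp by distance to the nearest protein-coding TSS in bp, negative upstream, with the median of those within 500 bp at -93 bp.

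Of the 21 gene lists fixed in advance, only the cytosolic ribosomal proteins passed the adjusted threshold against genes of the same length. Among 92 ribosomal protein genes, 68 had a summit in the locus against 34.6 expected, a ratio of 1.97 (exact stratified test, adjusted p = 2.42e-11). In both replicates' own lists 48 of the 92 loci held a summit. A summit lay within 500 bp of an own TSS in 51 of them, 55.4%, against 15.1% of all protein-coding genes. Strong peaks in these loci were often nearest other genes. The peak in the RpL3 locus (530.7) was 63 bp from CG17726, that in the RpL27 locus (402.2) was 106 bp from Idh3g, and that in the RpL35 locus (427) was intronic, 1096 bp from Tre1. No summit fell in the loci of RpL10, RpL10Aa, RpL10Ab and RpL15, which were among 24 members without a summit. Ribosomal protein genes are short and lie among other genes. With genes matched on the number of TSSs in the locus, the ratio was 1.57.

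Strong Araucan peaks lay in loci of Dpp, Notch, EGFR and Wnt pathway genes, and no pathway list passed the adjusted threshold in the main test. In the Dpp (BMP) pathway and dorsal ectoderm list 16 of 20 loci held a summit against 10.5 expected (exact p = 0.0116, adjusted p = 0.121). Its highest peaks, in the loci of the Smad gene Med (789.8) and the ligand gene gbb (782.6), were 10 bp from the TSS of Mnat9 and 108 bp from that of eIF6. In the Notch list 12 of 16 loci held a summit against 7.59 expected (exact p = 0.0328, adjusted p = 0.172). The repressor genes E(spl)m7-HLH and E(spl)m8-HLH share a peak of 505.3 that was 140 bp from the TSS of the co-repressor gene gro. With replicate 2's list alone, 15 of 16 Notch loci were bound (ratio 2.13, exact test, adjusted p = 2.06e-04), and with replicate 1's list alone the ratio was 1.98 (adjusted p = 0.105). With overlapping loci merged in the conservative list, 9 of 12 were bound (ratio 1.41, exact p = 0.14). Merging was not run on replicate 2's list, so its p-value counts neighbouring E(spl) loci that share summits as separate. The EGFR list had 13 of 16 against 9.05 (exact test, adjusted p = 0.244), led by intronic peaks of the feedback inhibitor aos (578.7) and the ETS repressor aop (496.4). The Wnt list had 14 of 18 against 10.5 (exact test, adjusted p = 0.285), with the receptor gene fz (614.9) and the transducer gene dsh (301.3) highest. The peak in the dsh locus was 946 bp from the TSS of CG1737 and 4327 bp from that of dsh. The Hedgehog list had 6 of 13 against 6.78 (exact test, adjusted p = 1), with boi (241.9) and inv (175.7) highest. When genes were matched on TSSs in the locus, a choice made after seeing the data, 8 lists passed, which were ribosomal proteins, Dpp, Notch, EGFR, Wnt, Hox, mesoderm and muscle structure, and the Iroquois complex. When each summit was given to its nearest TSS, with length matching kept, 7 did. Among them were EGFR (ratio 2.10, exact test, adjusted p = 0.00878), Notch (2.26, adjusted p = 0.00878) and Dpp (1.92, adjusted p = 0.0361). The Wnt (1.74, exact test, adjusted p = 0.055) and Hedgehog (1.29, adjusted p = 0.632) lists did not pass under that rule. Without flanks and matched on length, EGFR passed as well (11 of 16 against 5.08, exact test, adjusted p = 0.0114). With TSS matching, the expected counts of the passing lists other than ribosomal proteins fell below those without any matching (Hox 2.96 against 3.49). Those calls therefore do not allow for locus length.

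Among developmental regulators, summits lay in all Hox loci and in 1 proneural locus, and none of these lists passed the adjusted threshold in the main test. All 8 Hox loci held a summit against 5.11 expected (exact test, adjusted p = 0.239), with intronic peaks in Antp (244.7) and Ubx (132.3) highest. The count was 7 of 8 without replicate 1 and 5 of 8 without replicate 2. Only 1 of 11 proneural and sensory organ loci held a summit, against 4.46 expected (ratio 0.224, exact p = 0.0328, adjusted p = 0.172). The ratio was 0.643 with 10 kb flanks (4 of 11) and 0.559 with the nearest TSS, and without flanks no locus was bound against 0.699 expected. The locus bound with 5 kb flanks was emc, an inhibitor of proneural proteins (79.6), and neither ac nor sc, proneural targets in genetic work on the Iroquois complex and chosen here after their values were seen, held a summit. That absence covers 5 kb around each gene in whole embryos of 0 to 24 h, not sequence farther away or other stages. Of mesoderm and muscle structure loci 15 of 20 were bound against 11.4, led by the myogenic regulator Mef2 (612.4, 158 bp from the TSS of Pal1 and 1062 bp from that of Mef2) and the heart gene tin (511.6, 197 bp from its TSS). Muscle identity factors had 8 of 15 against 8.37, with org-1 (630) and tup (207.7, 163 bp from the TSS of CG10602) highest. Tracheal loci had 7 of 13 against 7.36, with rib (365.2) and grh (361.4). Gap and pair-rule loci had 6 of 17 against 7.85, with slp2 (563.1) and cad (207.8, 269 bp from the TSS of Pomp). Retinal determination loci had 5 of 10 against 5.96, with hth (194.9) and dac (112.4), and neuroblast factors 8 of 14 against 7.67, with brat (538.5) and grh. Adjusted p for these 6 lists ran from 0.289 to 1.

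Marker lists for differentiated or unrelated tissues stood near their expectation. Neuron markers had 8 of 15 bound loci against 9.34, with elav, a neuronal RNA-binding protein gene, at 465.7 in its promoter and Gad1 at 229.7. The peak in the Gad1 locus was 1091 bp from the TSS of wit and 15217 bp from that of Gad1. Hemocyte and fat body markers had 7 of 13 against 7.1, with ush (262) and Lsp2 (201.8, 56 bp from the TSS of yps). Endoderm and gut markers had 6 of 11 against 5.94, with bowl (476.6) and cad. Germline markers had 7 of 11 against 5.42, with bam (343.1, 5 bp from the TSS of RpS27) and nanos (233.3, 85 bp from that of Nsun5). Cell cycle genes had 7 of 13 against 6.46, with CycB (813.1) and fzr (322, 350 bp from the TSS of CG3009). Heat shock genes had 8 of 16 against 6.55. Hsp67Ba and Hsp23 share a peak of 651.8 that was 148 bp from the TSS of Hsp27. Adjusted p for these 6 lists ran from 0.789 to 1 in the exact test.

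**Figure D3:**
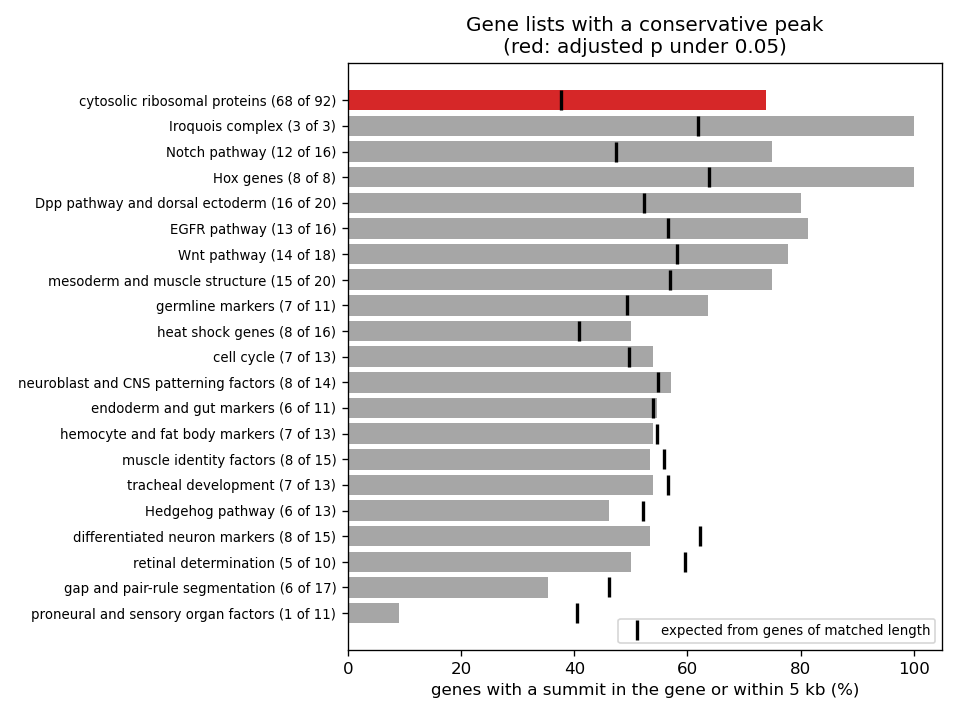
Percent of genes with a summit in the gene or within 5 kb for each of 21 lists, with counts in the labels and black ticks at the share expected from genes of matched length. Only the cytosolic ribosomal proteins (red, 68 of 92) passed the adjusted threshold.

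The known Iroquois recognition sequence was barely more frequent at summits than beside them. The palindrome ACANNTGT was in 4.80% of 4706 summit windows and 4.38% of flanking windows, an odds ratio of 1.10 (95% interval 0.934 to 1.30, Fisher's exact test, adjusted p = 0.336). The pentamer TAACA, fixed in advance as an Iroquois site, was more frequent at summits (24.5% against 18.2%, odds ratio 1.46, Fisher's exact test, adjusted p = 3.91e-17), and so was the control pentamer TACAA (27.6% against 20.5%, odds ratio 1.47, adjusted p = 2.35e-19). Summit windows had a lower GC share than their flanks on average, 37.2% against 42.6%, but not in the weakest of 4 signal groups, with 44.9% against 41.4%. Against random windows of matched GC share, the odds ratio was 1.24 for the palindrome (Fisher's exact test, adjusted p = 0.0409), 1.32 for the control palindrome ACTNNAGT (adjusted p = 0.0409), 1.11 for TAACA (adjusted p = 0.0409) and 1.02 for TACAA (adjusted p = 0.902). In the strongest signal group, the ratio of the TAACA to the TACAA odds ratio was 1.09 (95% interval 0.870 to 1.36), so no difference between them was resolved.

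The DREF and M1BP sites, bound by factors of promoters of broadly expressed genes, were more frequent at Araucan summits than in flanks, less clearly so in the stronger peaks. The DREF site TATCGATA was in 0.935% of summit windows and 0.255% of flanks (odds ratio 3.69, interval 2.23 to 6.0, Fisher's exact test, adjusted p = 6.03e-07). The M1BP site GGTCACACT had an odds ratio of 2.72 (Fisher's exact test, adjusted p = 0.00848). Without promoter summits the DREF odds ratio was 0.80. In the stronger peaks alone it was 2.34 (Fisher's exact test, adjusted p = 0.0622) and that of M1BP 1.60 (adjusted p = 0.53). The homeodomain core TAATTA (odds ratio 1.38, Fisher's exact test, adjusted p = 5.37e-06) and the GATA site WGATAA (1.21, adjusted p = 7.39e-04) were also more frequent than in flanks, but not than in windows of matched GC share (0.978 and 1.02). The control palindrome ACTNNAGT had an odds ratio of 1.41 (Fisher's exact test, adjusted p = 0.00848) and CATNNATG 1.16 (adjusted p = 0.231). The Mirror site ACACGTGT is one form of the palindrome ACANNTGT, so its windows are also counted there. It was less frequent at summits (2 of 4706 windows, odds ratio 0.222, Fisher's exact test, adjusted p = 0.0474), as was the repeat CACACACA (0.485, adjusted p = 7.92e-09). Against matched GC share the values were 1.33 and 1.03, and the Mirror call was also lost in the stronger peaks (Fisher's exact test, adjusted p = 0.252) and without replicate 1 (adjusted p = 0.341). Sites of the early activator Zelda (0.892, Fisher's exact test, adjusted p = 0.404), of GAGA factor (0.878, adjusted p = 0.377) and of TALE partners (1.02, adjusted p = 0.838) gave no call against flanks, but without replicate 1 the Zelda site was below them (0.750, adjusted p = 0.0414). In the stronger peaks the GAGA site was less frequent than in flanks (0.302, Fisher's exact test, adjusted p = 3.44e-07), as it was without replicate 1 (0.581) and without replicate 2 (0.460). Against windows of matched GC share the GAGA site had an odds ratio of 2.52 (Fisher's exact test, adjusted p = 8.17e-08).

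**Figure D4:**
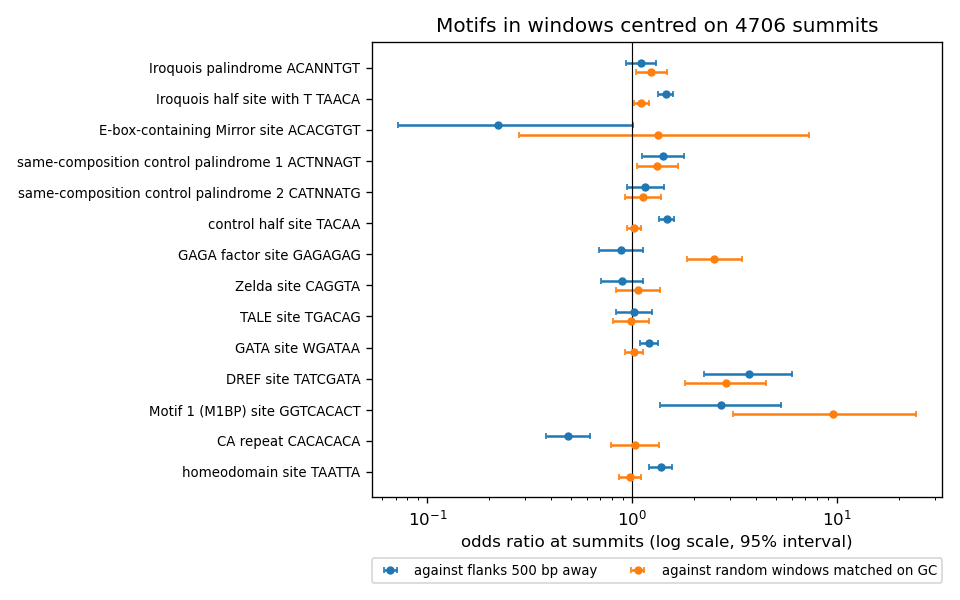
Odds ratios (log scale, points with 95% intervals) of 14 motifs in windows at 4706 summits, against flanks 500 bp away in blue and random windows of matched GC share in orange. The Iroquois palindrome lies at 1.10 against flanks, and DREF at 3.69.

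Stronger Araucan peaks were more often at promoters, while no trend with signal was resolved for the Iroquois palindrome. In 4 equal groups from the strongest to the weakest, 47.4% (95% interval 44.5 to 50.3), 38.4%, 37.9% and 35.9% (33.2 to 38.7) of summits were in promoters (Spearman's rho 0.086 across peaks, permutation p = 1e-05, the smallest possible). The palindrome was in 5.44%, 4.76%, 4.76% and 4.25% of windows (rho 0.0132, permutation p = 0.367). The GC share of the summit window, examined after seeing the data, was 31.0% ± 8.06 (SD, n = 1176 windows) in the strongest group and 44.9% ± 11.2 (SD, n = 1177 windows) in the weakest (rho -0.472). Peaks are not independent replicates.

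**Figure D5:**
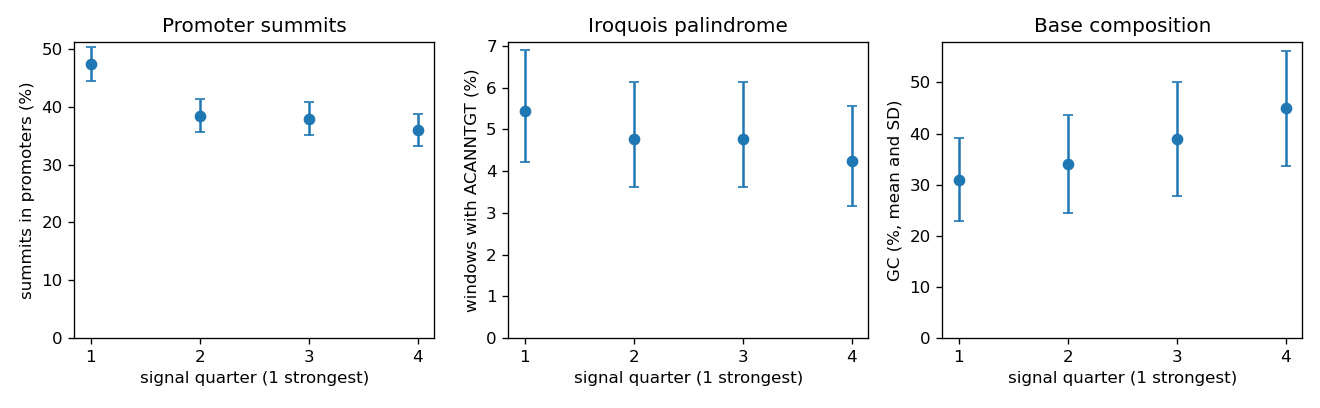
Share of summits in promoters, share of windows with ACANNTGT (both %, with 95% exact intervals) and GC share of the window (%, mean and SD) in 4 equal groups of peaks, the strongest at the left. GC share goes from 31.0% to 44.9% while the palindrome share lies between 4.25% and 5.44%.

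Chromosome 4, the small and largely heterochromatic arm, was nearly free of Araucan peaks. It held 4 summits, 2.97 per Mb (exact Poisson 95% interval 0.808 to 7.60), a density 0.0836 times that of the other arms (exact binomial test, adjusted p = 7.09e-15). The other arms held between 32.9 per Mb (X) and 37.8 per Mb (2L). The binomial tests and Poisson intervals take summits as independent, while summits cluster along the arms. The p-values for small differences between arms are therefore too low. The 2L arm (ratio 1.09) and 3L (1.09) lay above the rest (exact binomial test, adjusted p = 0.0389 for both), 2R (1.02) and 3R (0.946) gave no call, and X had a ratio of 0.923 (adjusted p = 0.0607). The 3L call was lost in the stronger peaks (1.02), without replicate 2 (1.02) and in the ranked list at the same score (1.06). The 3R arm passed without replicate 1 (0.900, exact binomial test, adjusted p = 0.00947). In the full ranked list, where most peaks are weak, 3L was below the rest (0.949, exact binomial test, adjusted p = 1.02e-15) and 3R above (1.08, adjusted p = 3.16e-38). There X was also above the rest (1.02, exact binomial test, adjusted p = 0.00136), and 2L gave no call (1.01, adjusted p = 0.0528). Chromosome 4 had a ratio of 0.0702 in that list, so peaks of any strength were few on it, not the conservative peaks in particular. Filtering by the authors or low mappability may set that density and was not tested.

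Peaks of replicate 1 were nearly all found again in replicate 2. Of 2396 replicate 1 peaks, 87.9% (95% interval 86.6 to 89.2) overlapped a replicate 2 peak, against 1.77% by shifting (permutation p = 0.001, the smallest possible). Of 4132 replicate 2 peaks, 50.8% (49.3 to 52.4) overlapped a replicate 1 peak. Among conservative peaks, 2113 were in both replicates' lists (median signal 166.2), 1236 in replicate 2's alone (87.4), 191 in replicate 1's alone (80.3) and 1166 in neither (66.0). Across 70311 matched peaks of the full ranked lists the replicate signals had a Spearman's rho of 0.419 and a Pearson's r of 0.526 on log2 signal. Across the 10000 of highest mean signal the values were 0.469 and 0.777. Across the 4407 at conservative peaks they were 0.749 and 0.854, but that list was selected for repeating between replicates.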

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

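Both results here were noticed only after the data were seen, because they lie in data that the comparisons did not use. Of the conservative peaks, 10 lay on unplaced scaffolds, all named for X, with a median signal of 79.1 and a highest signal of 203.9. The true-replicate ranked list held 123 peaks that reached the score of 830 and were not in the conservative list. They are counted here and not described further, and taking them in gave a promoter ratio of 2.95 and a ribosomal protein ratio of 1.94.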

How the results depend on the processing

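In all, 56 results gave 554 values under alternatives, of which 485 kept their side of the threshold or their size, 34 passed it newly, 18 no longer passed, 10 moved and 7 reversed. Direction was read only where a test passed in at least 1 of the settings compared. Some alternatives were chosen after seeing the data. The promoter ratio (2.17 to 4.09), the chromosome 4 ratio (0.0702 to 0.102) and the ribosomal protein ratio (1.57 to 7.91) kept their calls in every alternative run. For the rest the cause was not tested. The number of gene lists past the threshold (1) was 2 without flanks, 7 with the nearest TSS, 6 without length matching and 8 with TSS matching, and 1 to 2 with a replicate left out. With the nearest TSS the tracheal (2.35) and gap and pair-rule (2.21) lists went above expectation. The X ratio was past the threshold with the other thresholded list (0.921) and all ranked peaks at the same score (0.905), but was 1.06 in the stronger peaks, 1.04 without replicate 2, 0.977 without replicate 1 and 1.02 in the full ranked list. The palindrome's odds ratio passed with wider windows (1.18) and matched GC (1.24). Matched GC also turned the Mirror (1.33), GAGA (2.52), CACACACA (1.03) and TAATTA (0.978) sites, and leaving out promoters turned DREF (0.80). The 7 motifs more frequent at summits were 4 in the stronger peaks and 4 without promoters. Replicate rho was 0.749 at conservative peaks.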

Other observations

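Gene families picked by symbol after the data were seen differed widely in how often their loci held an Araucan summit. Mitochondrial ribosomal proteins had 38 of 73 loci with a summit against 25 expected from genes of their length (ratio 1.52, exact stratified test, adjusted p = 0.00556). The tRNA synthetases had 22 of 32 against 14.4 (ratio 1.53, exact test, adjusted p = 0.0124), and proteasome subunits 20 of 48 against 18.4 (adjusted p = 0.655). Odorant receptors had 8 of 59 against 24.1 (ratio 0.332, exact test, adjusted p = 4.14e-05), gustatory receptors 14 of 60 against 25.2 (0.556, adjusted p = 0.00781) and cuticle proteins 17 of 70 against 26.1 (0.651, adjusted p = 0.0316). The Jonah and trypsin proteases had 6 of 27 against 8.85 (exact test, adjusted p = 0.353). With summits within 1 kb of a TSS, the mitochondrial ribosomal proteins (14 against 8.14, ratio 1.72, exact test, adjusted p = 0.063) and the tRNA synthetases (8 against 6.47, ratio 1.24, adjusted p = 0.536) did not pass, on smaller counts. Under that rule odorant receptors (0.104), gustatory receptors (0.103) and cuticle proteins (0.208) still passed, and proteasome subunits had a ratio of 0.730.

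Sites of some insulator proteins were more frequent at Araucan summits than beside them, among 8 motifs added after the data were seen. The CTCF type site AGRKGGCGC was in 0.956% of summit windows and 0.266% of flanks (odds ratio 3.63, Fisher's exact test, adjusted p = 1.11e-06). The Su(Hw) type site TGCATACTT had an odds ratio of 2.51 (Fisher's exact test, adjusted p = 0.0142), the BEAF-32 type site TCGATA 1.49 (adjusted p = 3.35e-05), CGATA 1.18 (adjusted p = 0.00664) and CAATAAG 1.44 (adjusted p = 0.0203). CGATA lies within TCGATA, and TCGATA within the DREF site TATCGATA, so these counts overlap and cannot be told apart from DREF sites. The core site TAGCATA of Pita, also an insulator protein (1.17), CACGTG (0.848) and MCGCCATCT (1.33) did not pass. CACGTG lies within the Mirror site ACACGTGT, so these counts overlap too. Only the CTCF type site passed in every alternative (2.84 to 6.48). The calls were lost for CGATA in the stronger peaks (1.10), with either replicate left out (1.13 and 1.03) and without promoters (0.970), and for TCGATA without replicate 2 (1.12) and without promoters (0.931). They were also lost for Su(Hw) in wider windows (1.71) and without promoters (2.00), and for CAATAAG against matched GC share (0.959). The Pita core passed with either replicate left out (1.53 and 1.84).

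The tests in the next 3 paragraphs on single replicates, on chromosome 4 and on pooled families within 1 kb of a TSS were chosen after the values they measure had been seen, and the others before. The strongest peaks sit in AT-rich windows, with a GC share of 31.0% against 43.2% beside them. Base composition alone is argued against, since random windows matched on centre and flank GC lay in promoters in 15.1% of cases (interval 14.2 to 16) against 47.4% for the strongest peaks. The pattern was in both replicates, with the smaller difference at -12.2 percentage points. The lower GC share was not confined to windows with the pentamer TAACA, since the 798 windows without it differed from the flanks by -11.3 percentage points. A pentamer is too short a part of a window to make such a difference by its own bases. The comparison therefore could not have come out otherwise, and it does not test a role of the site. With promoter summits left out of the main list, the GC share was 36.9% against 41.45% beside them, so lower GC across the list was not confined to promoters. For the strongest peaks, a composition bias that acts only in open promoter chromatin may still contribute and was not tested, and the design gives no group for a biological test.

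Ribosomal protein loci held more summits than matched genes. Dense surroundings do not account for all of the excess, since with genes matched on TSSs in the locus the ratio was 1.57 (exact p = 1.24e-07). A signal common to promoters of broadly expressed genes may contribute, and this stays open. Pooled mitochondrial ribosomal protein, proteasome and tRNA synthetase genes had a ratio of 1.38 (exact p = 2.37e-04), and pooled receptor, cuticle and protease genes 0.534 (exact p = 7.07e-09), but with summits within 1 kb of a TSS the values were 1.26 (exact p = 0.191) and 0.126 (exact p = 8.65e-11), so the promoter part was not shown. The ribosomal protein ratio under that rule was 4.38 (exact test, adjusted p = 2.14e-24). Recovery of open promoters by any tagged protein was not tested, because control libraries were not used here.

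Chromosome 4 was nearly free of summits. Selection of strong peaks is argued against, since in the full ranked list, where most peaks are weak, its density was still 0.0702 times that of the other arms. A lack of promoters is argued against too, since 1.25% of its 80 protein-coding genes (interval 0.0316 to 6.77) had a summit within 500 bp of a TSS, against 15.1% on the other arms (Fisher's exact test, p = 5.51e-05). Filtering by the authors or low mappability may set the density of all peaks there and was not tested.

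Of the conservative peaks, 171 had a signal under 30, with a median of 7.74, and 166 of them had a summit within 250 bp of another conservative peak.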
